A study of Anopheles gambiae with 104 samples.

How the data were processed

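Total RNA of mated female Anopheles gambiae (Pimperena strain, S form) that had not taken blood was measured on Affymetrix arrays in 104 samples. Heads, with mouthparts and antennae, and bodies were separated from pools of 20 to 30 mosquitoes per time point, per the labels' protocols. Females were 7 to 9 days old at the start. They were kept either in a light:dark cycle (LD, 11 h of full light with 1 h dawn and dusk transitions) or in constant dark (DD). Each tissue and regime forms an arm of 13 time points 4 h apart over 48 h, with 2 arrays per time point. LD runs from zeitgeber time (ZT) 12, the hour of lights off, to ZT60, and DD from circadian time (CT) 0, subjective dawn, to CT48. The first collections of the regimes therefore lie 12 h apart after the last lights off. The labels do not say that the 2 arrays of a time point came from separate pools, so the spread between those 2 arrays may be technical. P-values of the main fits measure only the spread of these time points around the fit. For the main fits the 2 arrays were averaged and the time point was the unit.

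The deposited values are on the log2 scale, 1 per probe set and array, made by the authors with GCRMA (background correction by probe sequence, normalization between arrays and summary of probes into probe sets), per the submitters' processing notes. RNA was labelled with a 3′ in vitro transcription kit, per the labels' protocols. The GCRMA version, the probe definitions and which arrays were normalized together are not given in the sources used here. Values ranged from 0.69 to 15.63 and array medians from 2.89 to 3.18. The number of arrays limits the precision, and values near the array medians, among them the troughs of several named probe sets, lie close to those of the P. falciparum probe sets (median 3.09).

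The table holds 22761 probe sets. By their names 16884 belong to Anopheles, 4502 to the malaria parasite Plasmodium falciparum, which shares the array design, and 144 are array controls. The other 1231 carry an accession or another name, do not say which organism they belong to and were left out. The files do not pair probe sets with genes. The reference table used here lists 15165 genes of assembly idAnoGambNW_F1_1, and 0 probe set names matched any of its identifiers. The gene lists fixed beforehand (clock, olfactory, visual, detoxification, immune and others) could therefore not be assigned, and their tests were not run. Results are given for probe sets by ID, with at most 2 IDs in each direction per comparison, and by name only for the actin and Gapdh control probe sets. A probe set name gives a chromosome arm and a cluster number, and probe sets that share both are called partners here. Grouping by chromosome arm, by partners and by 4-fold difference between heads and bodies was chosen after the IDs were seen.

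Anopheles probe sets were kept when their mean over the arrays of a tissue lay above the 95th percentile of the P. falciparum probe sets (3.75 on the log2 scale in heads and 3.78 in bodies), since these females had not been blood fed. This left 7188 probe sets in heads, 7325 in bodies and 8438 in either tissue. Rhythm was tested per arm with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) as the F-test of the cosine and sine terms of a 24 h cosinor over 13 time point means, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fitted peak hour is the acrophase, and fold values of a rhythm are fitted peak over fitted trough. LD and DD were compared within a tissue in a joint limma fit of 26 time point means, with separate tests of the rhythm terms and of the mean level. Heads and bodies were compared as head minus body differences at each of the 13 time points. P. falciparum probe sets were run through the same fits as a negative control. The rule for named genes asked for a symbol, so it was applied to probe sets. IDs were ranked by fitted amplitude among called probe sets whose acrophases from each replicate alone lay within 4 h, by level difference with the same sign in both replicates, or by F. Overlaps and group shares were tested with two-sided Fisher exact tests, the group shares with Benjamini-Hochberg adjustment over 32 tests. Probe sets are not independent of one another, so these p-values describe the lists and not separate mosquitoes.

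The fits were tested on simulated data with 200 changed probe sets each, and the fits of rhythm ran on as many probe sets as the real ones. Of rhythms with an amplitude of 0.5 on the log2 scale, 86.6% were recovered in heads in LD, 80.6% in bodies in LD, 70.1% in heads in DD and 65.7% in bodies in DD, and at an amplitude of 0.25 the shares were 50.7%, 25.4%, 17.9% and 19.4%. For a rhythm present only in LD with an amplitude of 0.5, the LD and DD comparison recovered 61.2% in heads and 50.7% in bodies, and for a rhythm in heads alone the heads and bodies comparison recovered 47.8% in LD and 37.3% in DD. False calls made up 1.46% to 9.26% of the calls of a comparison, the highest in the rhythm test of heads against bodies in LD. Next were 7.84% for the LD and DD level in bodies and 6.92% for rhythm in bodies in DD. Noise was drawn independently for each probe set, while real probe sets are not independent. These rates therefore describe the simulation and need not hold for the real arrays.

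Before the data were examined, alternatives were fixed for the unit of the fit, a replicate block, each replicate left out, a linear trend, 12 time points, the filter, quantile normalization, the eBayes prior, ranks, a fold threshold, periods of 20 and 28 h, a 12-hour harmonic, and heads and bodies without pairing. After seeing the data, fits without CT44 of heads in DD, without ZT52 of bodies in LD and with a 3′ minus 5′ covariate were added. Arrays of the same time point correlated in their deviations from the arm mean (across probe sets, median r 0.62, 0.67, 0.56 and 0.42 in heads LD, bodies LD, heads DD and bodies DD), and arrays with the same replicate number at other time points did not (0.03, -0.06, -0.04 and -0.07). In deviations from the time point mean, same-numbered arrays of heads in LD did correlate for every pair of time points (median r 0.471, lowest 0.278). In bodies LD, heads DD and bodies DD the median r was 0.171, 0.0848 and 0.0465 and the lowest 0.00153, -0.131 and -0.233. The phe spike-in was higher on the replicate 2 array at 12, 13, 13 and 11 of 13 time points in heads LD, bodies LD, heads DD and bodies DD, without overlap in bodies LD (at most 3.72 against at least 5.96). In heads DD the Gapdh and actin 3′ minus 5′ differences were higher on it at 11 and 11. The numbers thus mark series of arrays in spike-in level. Deviations across probe sets were shared by every pair of time points in heads in LD, and only weakly in bodies in LD. No 2 arrays of the same arm held identical values.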

Results

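The arrays followed transcript levels of female mosquitoes over 48 h in heads and bodies, under a light:dark cycle and in constant dark. The series asks which transcripts follow a rhythm of about a day, first with light as a cue and then without it. Each of the 4 arms held 26 arrays at 13 time points.

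Control probe sets showed how the RNA on the arrays differed between arms. The array carries probe sets for the 3′ and 5′ ends of the glycolytic enzyme Gapdh and of the cytoskeletal protein actin. The Gapdh 3′ minus 5′ difference averaged 2.59 ± 0.20 on the log2 scale (SD, n = 13 time points) in heads in LD and 3.04 ± 0.46 in bodies in LD, against 4.40 ± 0.97 in heads in DD and 4.34 ± 0.58 in bodies in DD. For actin the averages were 2.25 ± 0.21, 2.09 ± 0.20, 3.29 ± 0.63 and 2.72 ± 0.36 in the same order. The bacterial dap transcript, a poly-A control added to RNA before labelling, gave 1.51 ± 0.20 in heads in LD, 0.87 ± 0.27 in bodies in LD, 2.73 ± 0.23 in heads in DD and 2.19 ± 0.32 in bodies in DD. In each tissue the lowest DD time point lay above the highest LD time point for dap (2.38 against 2.03 in heads, 1.74 against 1.54 in bodies). At CT44 in heads the Gapdh difference reached 7.54, while the next highest time point of that arm stood at 4.51. At ZT52 in bodies the 2 arrays differed most, with an SD of 0.58 across probe sets against a median of 0.33 over the time points of that arm. In bodies in LD the phe spike-in averaged 3.20 ± 0.34 (SD, n = 13 arrays) on replicate 1 arrays and 6.61 ± 0.43 on replicate 2 arrays.

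**Figure D1:**
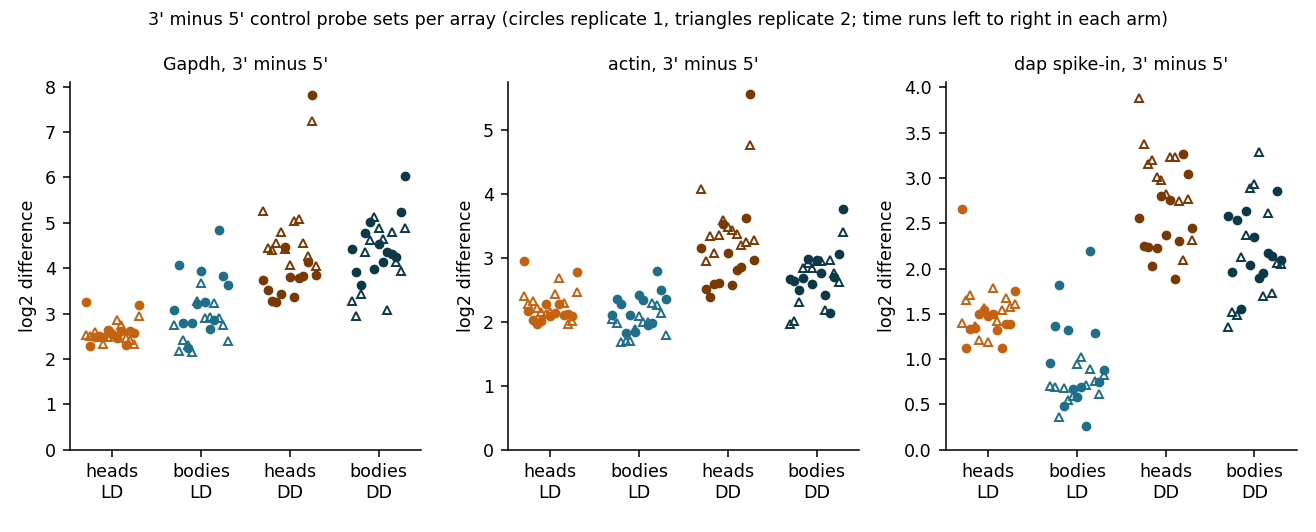
Difference between the 3′ and 5′ control probe sets of Gapdh, actin and the dap spike-in on the log2 scale (y axis) for each array of the 4 arms (x axis), with filled circles for replicate 1 and open triangles for replicate 2. The DD arms lie higher on average than the LD arms of the same tissue, with overlap between single arrays, and both arrays of CT44 in heads stand apart for Gapdh and actin.

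In heads under the light:dark cycle, many of the measured transcripts followed a daily rhythm. Of 7188 probe sets, 2657 (37.0%) were rhythmic, and their median change from trough to peak was 1.55-fold, with 637 changing at least 2-fold and 170 at least 4-fold. Peaks were most frequent from late night to early day, with 574 probe sets within 2 h of ZT20, 648 within 2 h of ZT0 and 418 within 2 h of ZT4. Within 2 h of ZT8 there were 256, and a smaller group of 404 peaked within 2 h of dusk at ZT12. Ag.3R.2620.0_at averaged 11.72 ± 0.12 on the log2 scale at ZT0 (SD, n = 2 time points) and 3.14 ± 0.21 at ZT12 (n = 3), with a fitted peak at 23.8 h and an adjusted p of 3.78e-06 (limma). Ag.2R.2131.0_CDS_at ran from 9.10 ± 0.11 at ZT16 to 3.95 ± 0.14 at ZT4 (adjusted p = 3.12e-07, limma). Peaking in the light, Ag.3L.1729.1_at stood at 8.98 ± 0.22 at ZT4 and at 2.58 ± 0.01 at ZT16 (adjusted p = 5.70e-06, limma), and Ag.2L.1186.0_CDS_at at 11.42 ± 0.05 and 7.00 ± 0.16 (adjusted p = 4.05e-06, limma). The 3 actin probe sets were rhythmic in this arm, the 3′ one with a 1.47-fold range and a peak at 2.57 h (limma p adjusted over the 24 control tests = 0.00023), while the 3′ Gapdh probe set ranged 1.07-fold (0.368). Replicates alone gave acrophases within 4 h for 99.1% of the rhythmic probe sets, which were called on the mean of both replicates. Of these 2657 probe sets, 1572 were also called on each replicate alone. Requiring a 1.5-fold change left 1451 probe sets.

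Bodies under the light:dark cycle held fewer rhythmic probe sets. Of 7325 probe sets, 1170 (16.0%) were rhythmic, with a median range of 1.97-fold, and 205 changed at least 4-fold. Peaks were most frequent in the morning, with 278 within 2 h of ZT0 and 310 within 2 h of ZT4, against 115 within 2 h of ZT8. Ag.2L.11.1_CDS_s_at averaged 12.12 ± 0.71 at ZT0 (SD, n = 2 time points) and 2.56 ± 0.23 at ZT12 (n = 3; adjusted p = 0.00164, limma), and its partner Ag.2L.11.0_CDS_at 13.50 ± 0.42 and 5.33 ± 1.15 (adjusted p = 0.0021, limma). At night Ag.3R.29.0_CDS_at averaged 9.76 ± 0.64 at ZT16 and 3.06 ± 0.31 at ZT4 (adjusted p = 0.000221, limma), and Ag.3R.20.0_CDS_at 13.22 ± 0.24 and 5.85 ± 0.57 (adjusted p = 0.00102, limma). None of the 6 actin and Gapdh probe sets was rhythmic in bodies in LD (lowest adjusted p 0.0738, Gapdh 3′, limma). Without ZT52, whose arrays stood apart, 1074 probe sets were rhythmic.

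In constant dark fewer probe sets were rhythmic in both tissues, and the counts depend on the fit. On ranks limma called 0 in heads and 0 in bodies (2073 and 1718 at an unadjusted p under 0.05), and a single replicate gave as few as 339 and 267. Arrays one by one with a replicate block gave 987 and 780 (997 and 798 without the block). In heads 641 of 7188 probe sets (8.92%) were rhythmic, with 184 peaks within 2 h of CT0, 142 within 2 h of CT12 and 64 within 2 h of CT4. Ag.3R.2620.0_at kept a daily swing, from 10.14 ± 0.81 at CT0 (SD, n = 3 time points) to 3.21 ± 0.25 at CT12 (n = 2; adjusted p = 0.000647, limma). Ag.2L.393.0_CDS_a_at ran the other way, with 11.39 ± 0.28 at CT12 and 6.54 ± 1.41 at CT0 (adjusted p = 0.00047, limma), as did Ag.3L.340.0_CDS_at with 8.29 ± 0.07 and 3.74 ± 0.39 (adjusted p = 0.00177, limma). In bodies 490 of 7325 probe sets (6.69%) were rhythmic, and 309 of them peaked in the subjective night. Ag.2R.93.0_CDS_at averaged 8.41 ± 0.08 at CT16 (n = 2) and 3.56 ± 0.06 at CT4 (adjusted p = 0.000106, limma), and Ag.2R.1248.2_CDS_a_at 7.28 ± 0.34 and 3.45 ± 0.25 (adjusted p = 3.98e-05, limma). Ag.2L.11.1_CDS_s_at remained rhythmic in bodies, at 11.15 ± 0.40 at CT0 (n = 3) and 8.09 ± 0.04 at CT12 (adjusted p = 0.000369, limma). The Gapdh and actin 3′ probe sets were not rhythmic in either DD arm, while 3 others were rhythmic in bodies in DD. They were the middle Gapdh probe set, with a 1.46-fold range (limma p adjusted over the 24 control tests = 0.00196), the middle actin one (1.32-fold, 0.0152) and the actin 5′ one (1.73-fold, 0.0277). The heads count fell to 395 when CT12 was left out and was 623 without CT44, where the 3′ minus 5′ difference was highest.

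**Figure D2:**
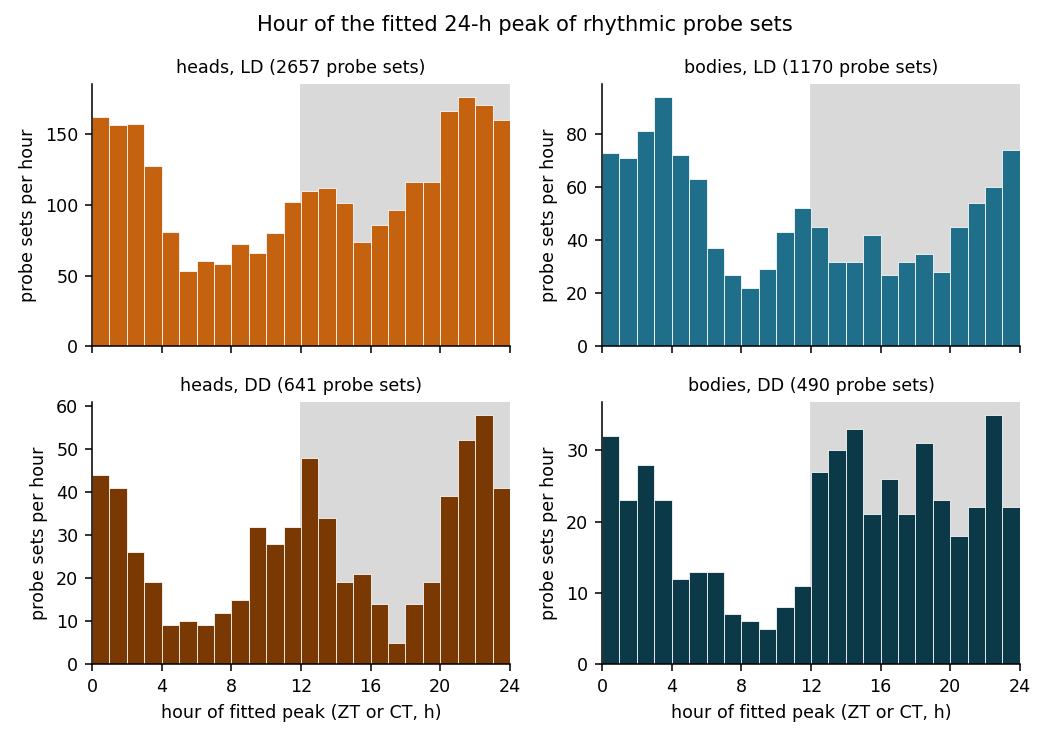
Number of rhythmic probe sets (y axis) per hour of the fitted peak (x axis, ZT in LD and CT in DD) in the 4 arms, with the dark hours or subjective night shaded. Heads in LD show a broad group around dawn and a smaller one near dusk, and bodies in LD peak mainly in the morning.

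No P. falciparum probe set was rhythmic in any arm after adjustment (limma). At an unadjusted p under 0.05 there were 9 of 4502 (0.2%) in heads in LD and 390 (8.66%) in bodies in LD. In DD there were 2 (0.044%) in heads and 461 (10.2%) in bodies. Chance alone would give a share of 0.05, so bodies lay above it and heads below it. These probe sets lie near background, so they do not show effects confined to brighter ones. Rhythmic partner probe sets peaked close together. In heads in LD, 304 pairs differed by a median of 0.45 h, and 92.4% lay within 2 h, against 18.5% of random pairs of rhythmic probe sets. The shares were 89.2% of 120 pairs in bodies in LD, 88.2% of 34 pairs in heads in DD and 81.2% of 32 pairs in bodies in DD.

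The rhythms of constant dark were largely those seen under light. In heads 544 of the 641 probe sets rhythmic in DD (84.9%) were rhythmic in LD too, against 237 expected of independent lists (Fisher exact test, p = 6.00e-152). In bodies it was 288 of 490 (58.8%), against 78.3 expected (Fisher exact test, p = 1.47e-113). Peak hours differed by a median of 1.201 h in heads and 1.33 h in bodies, and lay within 2 h of each other for 76.7% and 66.0% of the shared probe sets. Heads peaked earlier in DD by a median of -0.64 h, DD minus LD (quartiles -1.57 and 0.30 h), and bodies by -0.19 h (quartiles -1.56 and 1.04 h). Amplitude in DD over LD had a median of 0.841 in heads and 0.720 in bodies.

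**Figure D3:**
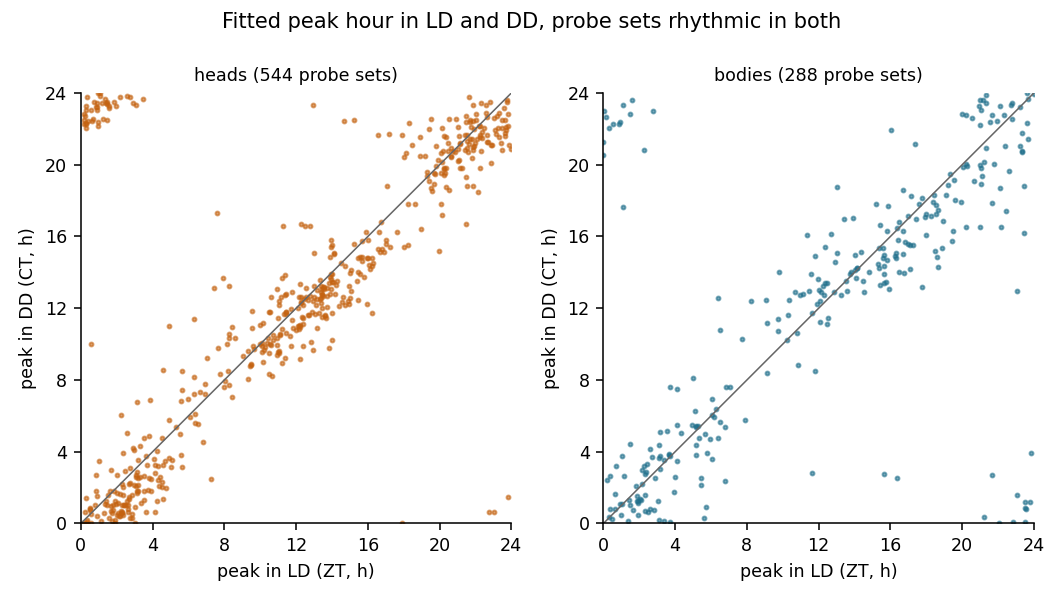
Fitted peak hour in DD (y axis, CT) against LD (x axis, ZT) for each probe set rhythmic in both, 544 in heads and 288 in bodies, with the line of equal hours. Points follow the line, and corner points are peaks on either side of hour 0.

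A direct test found rhythms that differed between the regimes, mostly with the larger amplitude under light. In heads 160 probe sets differed, 141 of them with the larger amplitude in LD, and in bodies 387 differed, 321 with the larger amplitude in LD. Ag.3L.25.0_CDS_a_at in heads changed 8.95-fold in LD and 1.46-fold in DD (adjusted p = 5.51e-06, limma), and Ag.3R.1554.0_CDS_at 6.98-fold and 1.12-fold (adjusted p = 1.32e-05, limma). Both peaked near dusk in LD, at 12.1 h and 12.6 h. In bodies Ag.2L.295.0_CDS_at changed 77.4-fold in LD, with a peak at 19.5 h, and 1.047-fold in DD (adjusted p = 5.29e-09, limma). The filter used the mean over both regimes, so a small range in 1 regime can also mean a signal near background there. Most calls made in LD alone did not pass this test: it held for 100 of 2113 in heads and 244 of 882 in bodies, so the remainder is not shown to differ. The heads count rose to 257 when CT8 in DD was left out and to 460 with arrays one by one and a replicate block (468 without the block). In bodies these fits gave 731 and 763. On ranks 1 probe set in heads and 0 in bodies differed (741 and 1160 at an unadjusted p under 0.05). On replicate 2 arrays alone it was 98 in heads and on either replicate alone 207 to 224 in bodies.

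Mean levels over the day differed between the regimes for most transcripts. In heads 5245 of 7188 probe sets differed, 2120 higher and 3125 lower in LD, of which 1822 differed at least 1.5-fold. In bodies 6277 of 7325 differed, 2803 higher and 3474 lower in LD, and 3881 differed at least 1.5-fold. Ag.3L.189.0_CDS_at was higher in LD in both tissues, at 10.59 against 2.51 in heads (adjusted p = 2.44e-33, limma) and at 11.80 against 2.42 in bodies (adjusted p = 1.41e-35, limma). Ag.3L.514.0_CDS_a_at was lower in LD in heads, at 3.87 against 10.89 (adjusted p = 1.78e-22, limma), and Ag.3R.2446.0_CDS_s_at was lower in LD in bodies, at 2.56 against 14.00 (adjusted p = 3.35e-15, limma). Levels under the filter cutoffs of 3.75 and 3.78, here and below, are not told from background, so only the direction of such a difference is taken from them. The 5′ Gapdh probe set averaged 10.13 ± 0.24 in heads in LD (SD, n = 13 time points) and 8.20 ± 0.88 in DD, and the 3′ one 12.72 ± 0.07 and 12.60 ± 0.14. Among P. falciparum probe sets 2806 of 4502 differed in level in heads and 1811 in bodies, and of these 0 and 8 differed at least 1.5-fold. Quantile normalization of all arrays of a tissue moved the median LD minus DD difference of bodies by 0.10 on the log2 scale and turned the balance there, with 3161 probe sets higher and 3122 lower in LD. The dap spike-in does not come from the mosquitoes, yet its 3′ minus 5′ difference parted the regimes. The lowest DD and highest LD time points were 2.38 and 2.03 in heads, and 1.74 and 1.54 in bodies. Processing thus differed between the regimes, and its part in the level differences cannot be told apart from light by this design.

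Heads and bodies differed in level for most transcripts and in rhythm for many. In LD 7845 of 8438 probe sets differed in level, 965 of them at least 4-fold higher in heads and 1314 at least 4-fold lower. In DD 7803 differed, with 838 and 1440 at least 4-fold higher and lower. Of 7300 probe sets that differed in both regimes, 6640 did so in the same direction. Ag.2R.429.0_CDS_at in LD averaged 13.11 in heads and 2.24 in bodies (adjusted p = 7.27e-23, limma), and Ag.3R.157.14_a_at 2.29 and 14.20 (adjusted p = 3.32e-21, limma). The direction of the smaller differences rests on the scaling: as deposited the median head minus body difference was -0.52 in LD and in DD, and quantile normalization of all arrays moved it by 0.48 and 0.56. With it, 3823 probe sets were higher and 4003 lower in heads in LD, against 2846 and 4999 as deposited. In DD it gave 3932 and 3767, against 2698 and 5105.

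In LD 1569 probe sets had a different rhythm in heads and bodies, and in DD 344 did. Of the 8438 probe sets tested, which passed the filter in either tissue, 6075 passed it in both. A different rhythm can therefore also mean a signal near background in 1 tissue. On ranks 1599 did in LD and 0 in DD (1373 at an unadjusted p under 0.05), and on a single replicate 1000 to 1135 did in LD and 194 to 195 in DD. Arrays one by one with a replicate block gave 629 in DD (638 without the block). Ag.2R.101.0_CDS_at changed 6.36-fold in heads in LD with a peak at 23.2 h and 1.06-fold in bodies (adjusted p of the difference = 1.34e-06, limma). In DD the night-peaking Ag.2R.2131.0_CDS_at changed 7.10-fold in heads, with a peak at 16.2 h, and 3.22-fold in bodies, with a peak at 19.2 h (adjusted p of the difference = 4.21e-05, limma). The test takes amplitude and peak hour together. This call was lost when heads and bodies were not paired by time point. Among probe sets rhythmic in both tissues in LD, 604 in all against 348 expected of independent lists (Fisher exact test, p = 5.46e-79), peak hours differed by a median of 1.49 h, and 49 peaked over 6 h apart. In DD 123 were shared, and bodies peaked later than heads by a median of 1.203 h. There were 85 probe sets rhythmic in all 4 arms, against 1.95 expected of independent lists, and in 64 of them all acrophases lay within 4 h of one another. Heads and bodies of a time point came from the same pooled mosquitoes and can share deviations. The expected numbers of independent lists do not allow for this.

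**Figure D4:**
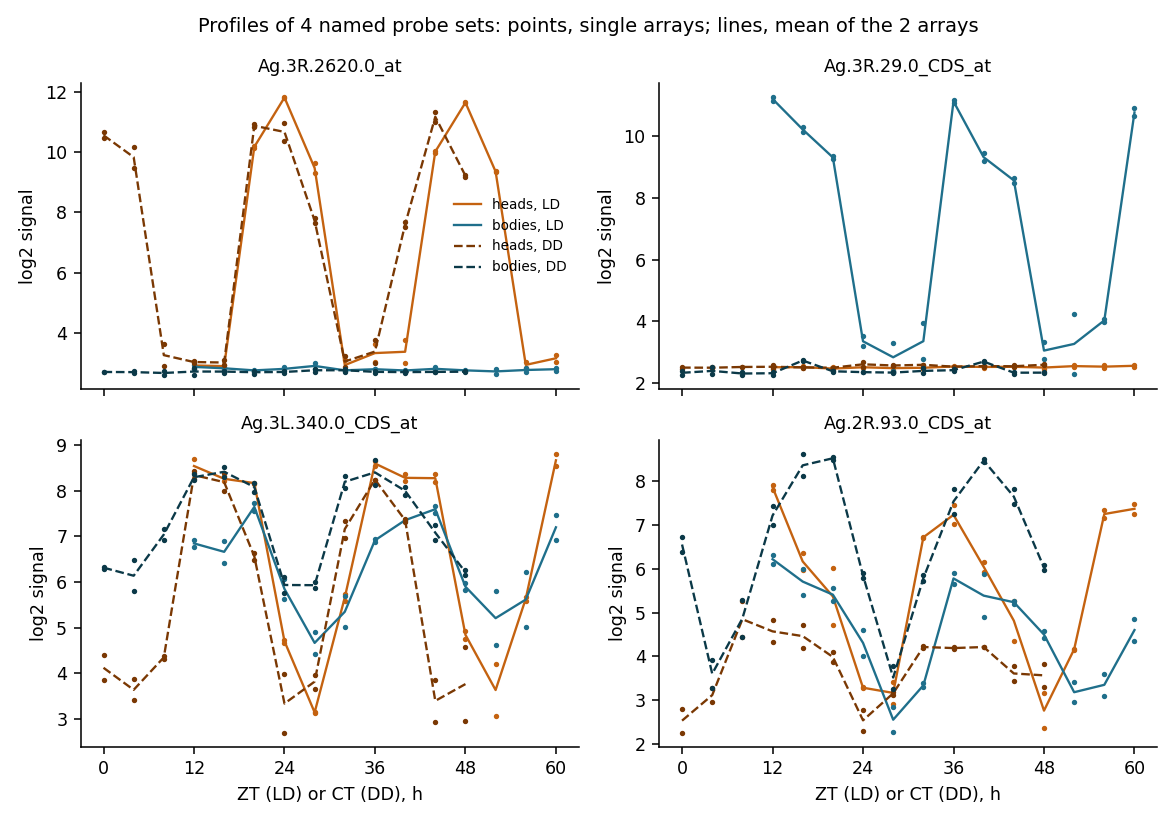
Log2 signal (y axis) over ZT or CT (x axis) of the probe set with the largest fitted amplitude of each arm that another arm had not already given, with single arrays as points, the mean of the 2 arrays as lines, and DD dashed. Ag.3R.2620.0_at swings in heads in both regimes, and Ag.2R.93.0_CDS_at swings in bodies in DD.

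Transcripts enriched in bodies were rhythmic more often than others. Of 1314 probe sets at least 4-fold lower in heads, 29.4% were rhythmic in bodies in LD against 13.04% of the others (Fisher exact test, adjusted p = 2.09e-41). In bodies in DD the shares were 12.7% and 5.37% (Fisher exact test, adjusted p = 9.17e-18). In heads in LD 44.1% of 624 such probe sets were rhythmic against 36.3% (Fisher exact test, adjusted p = 0.00166), a call that was lost on replicate 1 arrays alone (odds ratio 1.22, against 1.38). In heads in DD the shares were 10.9% and 8.73% and did not pass (adjusted p = 0.168). Probe sets at least 4-fold higher in heads did not pass the test in any arm (lowest adjusted p = 0.131, heads in DD, Fisher exact test). Probe sets whose name gives no chromosome (UNKN) were rhythmic less often in heads in LD, 28.9% of 332 against 37.4% (Fisher exact test, adjusted p = 0.0159), and passed in no other arm. Probe sets on chromosome X were rhythmic less often in each arm, with 32.3% against 37.4% in heads in LD, but did not pass the adjustment (adjusted p from 0.0857 to 0.113, Fisher exact test).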

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

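The tests of scatter, the splits after centring, the values without CT44 and the amplitudes along each day's phase were chosen only after the result or a related value had been seen. A test of the difference itself called rhythm differences in 160 probe sets between LD and DD in heads, in 387 in bodies, in 1569 between heads and bodies in LD and in 344 in DD, but on ranks in 1, 0, 1599 and 0. P. falciparum probe sets, used otherwise only for the filter and as a control, differed in level between LD and DD in 2806 cases in heads and 1811 in bodies.

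Chance was tested with 100 arrangements per result, the real one included. For rhythm counts only 1 of 100 time orders, the real one, gave as many, with 2657, 1170, 641 and 490 against at most 625, 39, 20 and 56 in heads LD, bodies LD, heads DD and bodies DD. For rhythm differences between heads and bodies it was also 1 of 100, with 1569 against at most 262 in LD and 344 against at most 30 in DD. For the level differences the real arrangement was again the only one of 100 to reach its count, with 5245 against at most 2497 in heads, 6277 against 5401 in bodies, 7845 against 6929 in LD and 7803 against 5692 in DD. Exchanging regimes among time points of one hour of the day gave as many rhythm differences as the real 160 in 3 of 100 splits in heads (highest other 2186) and as the real 387 in 5 of 100 in bodies (highest other 3350), so for bodies chance was not excluded there. Splits with several times the real count point to a structure of the samples, the level difference between regimes, which uneven splits turn into rhythms. After each regime was centred on its own mean, only the real split, 1 of 100, reached its count, with at most 2 in heads and 1 in bodies.

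Mean levels differed between LD and DD for most transcripts. Of the called probe sets, 98.3% in heads and 99.5% in bodies had the same sign in both replicate series. They were called on the mean of both series, which favours 1 sign, so this does not decide on the run of the replicate series. A batch of each regime has support in heads, where the share of mosquito probe sets that differed was 1.17 times that of P. falciparum ones. The median differences there were 0.31 and 0.07 on the log2 scale. In bodies the ratio of shares was 2.13. The dap spike-in also parted the regimes in both tissues, so processing differed between them. Its part in the level differences cannot be told apart from light. Stronger 3′ bias in DD gave the right sign for 60.0% of called probe sets in heads and for 51.9% in bodies. The prediction used each probe set's slope on the 3′ minus 5′ measure within the arms. Noise in these slopes moves the shares toward that of random signs, so the shares do not decide in either tissue. The 3′ bias predicted a median of 0.0854 of the difference in heads and 0.0108 in bodies. In heads 3722 probe sets still differed with the 3′ minus 5′ covariate (chosen after seeing the data). In heads these slopes lean on CT44 in DD, where the Gapdh difference was 7.54 and at the next highest time point 4.51. The heads values therefore do not decide, and 3′ bias stays open there. In bodies the value argues against 3′ bias as the whole source, as far as the slopes within arms hold between the regimes. A part stays open in bodies too.

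Fewer probe sets were rhythmic in DD than in LD. In bodies the median residual SD in DD over LD was 0.914, which goes against larger scatter. Yet simulated rhythms of amplitude 0.5, with each arm's scatter, were recovered at 65.7% in bodies in DD and 80.6% in LD. Larger scatter is therefore undecided in bodies. In heads the ratio was 1.43, and larger scatter stays open beside the lower amplitude. Among probe sets called on LD replicate 1 arrays, the replicate 2 amplitude in DD over LD was 0.681 in heads and 0.454 in bodies, so lower amplitude in DD may account for part of the loss. Selection on LD does not make all of it, because among probe sets called on DD replicate 1 arrays that ratio was 0.838 and 0.832. Damping is a candidate explanation in heads, where amplitude along the LD phase on day 2 over day 1 was 0.708 in DD and 1.03 in LD. The earlier peaks of day 2 lower this value (0.786 in DD along each day's median phase). Day 2 of heads in DD also holds CT44, and the amplitudes were not recomputed without it. Both days share their common time point at 24 h. Damping is undecided in bodies, with 0.781 and 0.862.

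Peaks came earlier on the second day in the dark. A free-running period under 24 h predicts this, and from day 1 to day 2 the median phase moved by -1.75 h in heads and -0.905 h in bodies in DD relative to LD. In heads 87.1% of the shared probe sets moved earlier in DD and 44.9% in LD, in bodies 78.8% and 64.2% (LD shift -0.31 h), and without CT44 the DD shift was -1.58 h against -1.70 h with it. The most calls in DD at any tested period were 1.56 times those at 24 h in heads (999 at 21 h against 641) and 1.06 times in bodies, which does not decide there. In LD, where the light cycle is 24 h long, heads gave the most calls at 25 h (2672 against 2657), so the scan does not place a period to within 1 h, and a shorter period is only a candidate explanation.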

How the results depend on the processing

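The counts and phase differences were recomputed under the alternatives, 228 values in all, of which 160 stayed within 1.5 times of the count, or within the spread between replicates of the phase difference. The others follow, beside the values of the report, and their cause was not tested except where stated. Of 814 values of single probe sets, shares and groups, 757 kept their call and direction, whatever their size, or for shares and counts their range. Single probe sets were picked for a large amplitude, difference or F, which favours keeping a call. Of the others 30 moved, 25 newly passed a test and 2 lost their call. The lost calls were the odds ratio of body-enriched probe sets in heads in LD without replicate 2 (1.22), and the rhythm difference of Ag.2R.2131.0_CDS_at in DD without pairing heads and bodies. None of the 814 reversed direction. Quantile normalization turned the balance of higher and lower probe sets in LD against DD in bodies and in heads against bodies in DD. The eBayes prior, the stricter filter, quantile normalization, heads and bodies without pairing and the fits without ZT52 (chosen after seeing the data) left the counts and phase differences they cover in that range.

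Replicate numbers mark series of arrays in spike-in level. Deviations across probe sets were shared by every pair of time points in heads in LD, and only weakly in bodies in LD. With arrays one by one and time point as a random block, counts in DD were 997 in heads and 798 in bodies, LD and DD rhythm differences 468 and 763, heads and bodies differences in DD 638, and phase differences 1.295 h and 1.64 h. With a replicate block added they were 987, 780, 460, 731, 629, 1.27 h and 1.64 h. Against the same fit without it, the block moved none of them by over 1.5 times. With no block, which takes arrays as independent, they were 1652, 1120, 682, 1189, 881, 1.37 h and 1.79 h, and bodies in LD 2111.

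On one replicate alone, with fewer arrays by construction, counts were 339 to 445 in heads in DD and 267 to 275 in bodies in DD, LD and DD rhythm differences 98 to 129 in heads and 207 to 224 in bodies, heads and bodies differences 1000 to 1135 in LD and 194 to 195 in DD, and phase differences 1.12 to 1.14 h in heads and 1.16 to 1.25 h in bodies. Phase differences in heads and bodies were 1.34 and 1.26 h with a linear trend, 1.16 and 1.22 h with 12 time points, 1.08 and 1.19 h without a filter, and 1.03 and 1.41 h with the 3′ minus 5′ covariate; in heads they were 1.14 h with the fold threshold and 1.09 h without CT44, the covariate and CT44 being chosen after seeing the data. With 12 time points 239 probe sets differed in rhythm between LD and DD in bodies, and with a 12-hour harmonic 259 did in heads.

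Without a filter, which tests more probe sets, counts in DD were 409 in heads and 307 in bodies, heads and bodies rhythm differences in DD 211, and level differences 13639 between LD and DD in bodies and 13564 (LD) and 15089 (DD) between heads and bodies. A 1.5-fold threshold, stricter by construction, left 1451 in heads in LD and level differences of 1822 in heads and 3881 in bodies. On ranks limma called 0 probe sets in heads and 0 in bodies in DD (2073 and 1718 at an unadjusted p under 0.05), 1 and 0 differences between LD and DD (741 and 1160) and 0 between heads and bodies in DD (1373). At 20 h limma called 0 in heads and 0 in bodies in LD (1175 and 866 unadjusted) and 41 in bodies in DD; at 28 h it called 1540, 5, 3 and 1 in heads LD, bodies LD, heads DD and bodies DD. Gene lists and their alternative of all probe sets were not run, since no probe set could be paired with a gene. Signal over background limits what was tested, since 7188 and 7325 of 16884 probe sets passed the filter.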

Other observations

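The grouping by 4-fold difference between heads and bodies was chosen after the IDs were seen, and the tests of brightness and of partner probe sets were planned before their results were. Of 29 probe sets that differed at least 16-fold between LD and DD in heads, 17 were higher in LD. Of these 29, 19 were measured in bodies, where 17 had the same direction and 11 differed at least 16-fold the same way. Of 187 such probe sets in bodies, 101 were higher in LD, 37 were measured in heads and 31 had the same direction there.

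A sequence difference under single probe sets could give such gaps. Only 11 of the 29 in heads and 35 of the 187 in bodies had a measured partner. The partners had the same sign for 11 in heads and 34 in bodies. For these probe sets this argues against a difference confined to 1 probe set, if partners do not share probes. The sources used here do not say whether they do. For the others it stays open, and a sequence difference that reaches both partners was not tested. Partners that both differed at least 16-fold were counted for each other. The partners showed a median of 0.778 of the difference in heads and 0.837 in bodies. The sizes can rest on levels under the filter cutoffs, so the argument is drawn from the sign only.

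That probe sets enriched in bodies were rhythmic more often might come from a brighter signal. Against other probe sets matched on mean level in 20 bins they were rhythmic 1.99 times as often in bodies in LD, 29.4% against 14.8%, which argues against brightness as the cause.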
